A study of Homo sapiens with 18 samples.

How the data were processed

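SLAM-seq was run on total RNA of HEK293T cells in 18 samples: DMSO or STM2457 for 3 h, then 100 µM s4U for 90 or 180 min or no s4U, with 3 samples for each combination. Per the labels' protocols, 5 µg of RNA was alkylated with iodoacetamide, 3′ mRNA libraries were made with the Lexogen QuantSeq forward kit and 15 PCR cycles, and 24 libraries were pooled and read in 1 direction for 114 cycles. The labels state that 1 library had a lower input than the rest, and do not allow it to be matched to a sample. Of the pooled libraries, 18 belong to the samples described here. Libraries of this kind read the 3′ end of polyadenylated RNA, and T-to-C conversions in the reads tell new RNA from old.

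Per the submitters' processing notes, FastQC 0.11.9 and STAR 2.7.8a were used with GRCh38.p12. The tool that fitted the kinetics, the annotation and the gene filter are not given in the sources used here. The deposited table holds 1 half-life and 1 synthesis rate per gene and treatment, with no column for a single sample or labelling time; which libraries entered each fit is not given in the sources used here. The authors also deposited log2 ratios of STM2457 over DMSO; recomputed from the half-lives in the table, these differed by at most 1.27e-14 over 8996 genes. The file headers name no time unit. Hours are inferred, because half-lives in the table stop at 69.3, which is ln 2 over a decay rate of 0.01, and because short-lived mRNAs such as MYC, chosen after its values were seen, at 0.653 in DMSO, take values that fit hours; any value in hours rests on this. The table gives no counts, so depth and its precision are unknown.

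The measure was the log2 ratio of the STM2457 half-life to the DMSO half-life. Genes past 1.5-fold were counted in each direction. No test was made, since each treatment has 1 value per gene. Values within 1e-06 of the largest half-life were taken as at the ceiling. The abundance implied by a fit was the synthesis rate divided by the decay rate.

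The text names genes by a rule: METTL3; the 10 largest and the 10 smallest log2 ratios among genes past 1.5-fold with both half-lives between 0.5 and 24 h; in that range, the highest and the lowest member of each list with at least 5 genes, and up to 4 each way for m6A factors and immediate early regulators; and the 3 genes with the most far coding motifs. The groups, tests, lists, named-gene rule and first set of alternatives were fixed before the data were examined. There were 20 gene lists, of which 18 had at least 5 genes. A list's median was placed among 10000 random lists of equal size from the other genes, drawn in 10 bins of the mean log2 half-life of both treatments. Motif classes and groups by gene structure were drawn with replacement, and a class holding over 50% of the genes was given no percentile.

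Motifs came from GENCODE release 29 (GRCh38), a release that differs from the one behind the table: 8982 of 8996 identifiers matched without their version, 3241 with it, and 8899 symbols were equal. For 8527 genes the transcript with the longest coding sequence was used; 98.8% of these sequences began with ATG and 99.3% were followed by a stop codon. DRACH motifs were counted by the position of their A and its distance to the nearest exon junction, with classes of 0, 1 to 3, 4 to 9 and 10 or more.

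The list procedure was tested on simulated lists of 30 genes from the 8996 genes. Of 200 unshifted lists, 5% lay outside the central 95%, and 68% of 50 lists shifted by 0.5 lay above it, with a mean excess of 0.52. These lists held random genes with ratios shuffled within bins, so they do not cover lists whose genes vary together. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Alternatives changed the range of half-lives, the matching, the size rule, the summary, the distance to a junction, the motif and the set of genes. Genes on the Y chromosome and XIST were left out of the named genes, and some genes that the rule names are not reported here.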

Results

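RNA decay was measured by SLAM-seq in HEK293T cells, a human embryonic kidney cell line, with and without STM2457, a small-molecule inhibitor of METTL3, the enzyme that deposits most N6-methyladenosine (m6A) on mRNA. In SLAM-seq, cells take up 4-thiouridine (s4U), and chemical alkylation of the s4U marks newly made RNA as T-to-C conversions in the reads. Cells received STM2457 or the solvent DMSO for 3 h, and then 100 µM s4U for 90 or 180 min or no label. Each of the 6 combinations had 3 samples, 18 in all. The deposited table gives 1 half-life and 1 synthesis rate per treatment for each of 8996 genes. It has no replicate values, intervals or read counts, so depth per sample is unknown, no p-value can be given, and every difference below is a difference between 2 fitted values. Genes are described as longer-lived or shorter-lived where the ratio of STM2457 to DMSO passed 1.5-fold, a fixed rule of size. The table does not name its time unit; hours are inferred from the values.

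The first comparison asked how inhibition of METTL3 moved mRNA half-lives as a whole. METTL3 mRNA itself (ENSG00000165819.12, chromosome 14, 21498133 to 21511375) had a half-life of 4.00 h in DMSO and 3.51 h in STM2457, a log2 ratio of -0.19; the compound acts on the protein. The longest shifts within the range of 0.5 to 24 h were in PELO, a factor that rescues stalled ribosomes, from 0.775 to 23.3 h (30.1-fold longer), and TBCC, a tubulin-folding cofactor, from 0.649 to 12.5 h (19.3-fold longer). BRMS1L, a component of histone deacetylase complexes, had the largest shift the other way, from 19.7 to 2.26 h (8.74-fold shorter), followed by MRPL39, a mitochondrial ribosomal protein, from 19.2 to 2.81 h (6.82-fold shorter). In all, 2562 genes (28.5%) were longer-lived and 2244 (24.9%) shorter-lived.

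PELO lies on chromosome 5 (52787940 to 52804046, GRCh38) and TBCC on chromosome 6 (42744481 to 42746096). The other genes among the 10 with the largest ratios in that range included SCAF8, which binds RNA polymerase II, from 1.35 to 22.1 h, and DCLRE1B, a nuclease that protects telomeres, from 1.48 to 24.0 h. ZRANB1, a deubiquitinase, went from 1.72 to 22.4 h, and RNF168, a ubiquitin ligase of the DNA damage response, from 1.85 to 20.4 h. PARS2, the mitochondrial prolyl-tRNA synthetase, had 1.12 h in DMSO and 13.5 h in STM2457, RTL6 had 1.96 and 21.1 h, and THAP12 had 2.17 and 23.0 h. ADAT3, a subunit of a tRNA adenosine deaminase, was 17.6-fold longer-lived, a value that is uncertain because the gene overlaps SCAMP4 on the same strand. TBCC, ADAT3, PARS2 and RTL6 carry their coding sequence in 1 exon, with 0 junctions inside it. Fitted synthesis rates, STM2457 over DMSO, had log2 ratios below 0 in all 10 genes, from -1.17 (TBCC) to -0.63 (ADAT3). Quartiles of that ratio over all genes were -0.37 and 0.28. The fitted synthesis rates and half-lives of all 10 genes imply steady-state abundances in STM2457 above what 6 h of synthesis without decay could reach. For PELO this was 14.8-fold its DMSO level, against 6.37-fold. The size of these shifts stays open. Among genes named below, HOXB6, MRPL44, ZNF628, ZC3H13, XPC, UPF3A, LSM1, DANCR and COL1A1 exceed that bound too, so their sizes also stay open. NDUFA5 and IFITM1, within 1.5-fold, exceed it as well, while YTHDF1, METTL14, NCOA6 and CHAC1 stayed under it.

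BRMS1L lies on chromosome 14 (35826318 to 35932325) and MRPL39 on chromosome 21 (25585656 to 25607517). Among the other genes with the smallest ratios, FAAP100, part of the Fanconi anaemia core complex, was 5.75-fold shorter-lived, NDUFAF7, an assembly factor of respiratory complex I, 5.65-fold, and ANGEL1 5.52-fold. EIF2B3, a subunit of the translation factor eIF2B, was 5.50-fold shorter-lived, PACSIN3 5.28-fold, and HCFC1, a transcriptional coregulator, 5.27-fold. MT-TL1, a mitochondrial transfer RNA, was listed at 21.3 h in DMSO and 3.20 h in STM2457, from libraries that read polyadenylated RNA. AC012254.2 was 5.66-fold shorter-lived, but it overlaps HDHD2 and IER3IP1 and is uncertain. Log2 synthesis ratios were above 0 in these genes, 2.26 for BRMS1L, except in FAAP100 (-0.71) and MT-TL1 (-0.64). Half-life and synthesis come from the same fit, so a trade-off between them stays open at both ends. The bound of 6 h of synthesis limits only rises. For these genes the fits imply 0.0965-fold (MT-TL1) to 0.55-fold (BRMS1L) the DMSO abundance. No lower bound was set, so these sizes stay open too.

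Over all genes, the median half-life was 5.61 h in DMSO (quartiles 2.99 and 10.4 h) and 5.39 h in STM2457 (quartiles 3.13 and 11.8 h). The median log2 ratio was -0.01, with quartiles of -0.58 and 0.73. The Spearman correlation of both half-lives across genes, which are not independent replicates, was 0.654. The table has a ceiling of 69.3 h, reached by 229 genes in DMSO, by 980 in STM2457 and by 163 in both. Of the longer-lived genes, 752 sat at the ceiling in STM2457, so the size of their ratios is set by the ceiling and stays open. Longer-lived genes were 53.3% of all genes past 1.5-fold, and 42.6% (1499 longer, 2022 shorter, median log2 ratio -0.16) when both half-lives had to lie between 0.5 and 24 h. That range selects on the outcome, since 1409 genes exceeded 24 h in STM2457 and 702 in DMSO. It thus removes more longer-lived than shorter-lived genes.

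**Figure D1:**
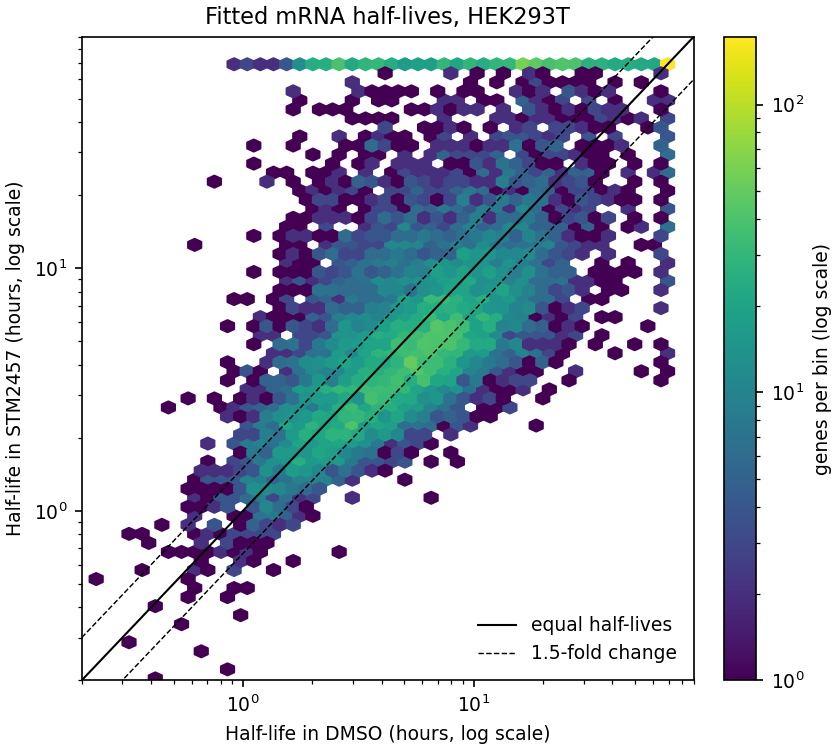
Half-life in STM2457 (vertical, hours, log scale) against half-life in DMSO (horizontal, hours, log scale) for 8996 genes, with colour for the number of genes per bin on a log scale. The solid line marks equal half-lives and the dashed lines a 1.5-fold difference; the row of bins at 69.3 h holds the 980 genes at the ceiling in STM2457.

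The second comparison asked which groups of genes held more longer-lived or more shorter-lived members. Zinc-finger transcription factors with numbered ZNF names, HOX genes, m6A factors and chromatin regulators with long coding exons had medians above matched random lists. Matched on the DMSO half-life, HOX genes (80.6th percentile) and chromatin regulators (85.2) no longer did. Within 0.5 to 24 h, HOX genes (96.7) and m6A factors (71.3) no longer did. That range also removes genes for their STM2457 half-life, among them 7 m6A factors at the ceiling. Of 153 ZNF genes, 71 were longer-lived, 17 shorter-lived and 65 within 1.5-fold, with a median log2 ratio of 0.50 and median half-lives of 1.79 h in DMSO and 2.49 h in STM2457. ZNF628 went from 1.66 to 14.0 h (8.48-fold longer) and ZNF76 from 10.5 to 3.47 h (3.04-fold shorter). Mitosis genes and proteasome subunits had medians of -0.71 and -0.53, below matched random lists; proteasome subunits lay at percentile 8.11 when matched on the DMSO half-life and at 2.74 within 0.5 to 24 h, inside the central 95%.

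Of 27 HOX genes, the patterning transcription factors, 12 were longer-lived, 2 shorter-lived and 13 within 1.5-fold (median 0.52). HOXB6, at 1.93 h in DMSO and 16.9 h in STM2457, and HOXA6, at 1.19 and 0.741 h, mark the ends of the list within the range; they overlap HOXB3 and HOXA3 on the same strand and are uncertain. The list of 33 chromatin regulators was fixed as those with long coding exons, with a median of 56 far coding motifs. Among its members, 15 were longer-lived, 5 shorter-lived and 13 within 1.5-fold (median 0.40). Genes with 40 to 79 such motifs had a median of 0.68 and those with 80 or more 0.41. The list was not matched on motifs, so its place is not shown to belong to chromatin regulators as a class. NCOA6, a nuclear receptor coactivator that overlaps PIGU, was 3.97-fold longer-lived.

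Among 19 m6A writers, erasers and readers, 10 were longer-lived, 2 shorter-lived and 7 within 1.5-fold (median 0.92). YTHDF1, a reader of m6A, went from 1.95 to 6.92 h, and the writer-complex genes ZC3H13, METTL14 and CBLL1 were 3.26-fold, 2.20-fold and 1.89-fold longer-lived. VIRMA, also of the writer complex, and the reader YTHDC2 were 1.63-fold and 1.61-fold shorter-lived, while IGF2BP3 and IGF2BP1 had log2 ratios of -0.54 and -0.46, within 1.5-fold. A further 7 members reached the ceiling in STM2457 and were chosen after their values were seen: WTAP, RBM15, RBM15B, YTHDF2, YTHDF3, HNRNPC and HNRNPA2B1. Among them HNRNPA2B1, at 49.6 h in DMSO, stayed within 1.5-fold. YTHDF2 had 1.33 h in DMSO and the ceiling of 69.3 h in STM2457. Within 0.5 to 24 h, which leaves these 7 out, the median of the list was -0.01.

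Of 28 mitosis genes, 16 were shorter-lived, 2 longer-lived and 10 within 1.5-fold. CDC20, an activator of the anaphase-promoting complex, went from 9.40 to 2.87 h (3.28-fold shorter). CENPA, the centromeric histone, was 1.85-fold longer-lived but overlaps SLC35F6. The median log2 ratio of synthesis rates for the same list was -0.18. Of 32 proteasome subunits, 15 were shorter-lived, 5 longer-lived and 12 within 1.5-fold; PSMC1 was 3.82-fold shorter-lived and PSMD10 1.53-fold longer-lived. Of 73 mitochondrial ribosomal proteins, 31 were shorter-lived, 20 longer-lived and 22 within 1.5-fold (median -0.33), from MRPL39 to MRPL44. MRPL44 was 9.80-fold longer-lived, a size that stays open. Its fit implies 7.56-fold its DMSO abundance, against 2.72-fold that 6 h of synthesis without decay could reach.

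Cytosolic ribosomal proteins were the most stable group. Of 73, 43 were at the ceiling in DMSO, 57 in STM2457 and 41 in both, where the ratio is 0 by construction. Their count was 14 longer-lived, 7 shorter-lived and 52 within 1.5-fold. RPL28 had half-lives of 12.8 h in DMSO and 13.0 h in STM2457. Of 71 nuclear-encoded respiratory chain genes, 17 were at the ceiling in DMSO and 34 in STM2457; 21 were longer-lived, 12 shorter-lived and 38 within 1.5-fold, with NDUFV2 2.30-fold shorter-lived and NDUFA5 at a log2 ratio of 0.12.

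Each list's median was placed among 10000 random lists of equal size matched on the mean log2 half-life of both treatments. Of 18 lists with at least 5 genes, 4 lay above the central 95% (ZNF at the 100th percentile, HOX at 99.7, m6A factors at 99.6, chromatin regulators at 99.7). Another 5 lay below it (mitosis at 0.07, proteasome at 0.07, cytosolic ribosomal proteins at 0, respiratory chain at 0.20, mitochondrial ribosomal proteins at 0.89). If the genes of a list varied independently, 0.9 of 18 would lie outside. Genes of a list need not do so, and this number is no test. The places of cytosolic ribosomal proteins and respiratory chain genes are uncertain, since 41 of 73 and 13 of 71 genes were at the ceiling in both treatments. Without ceiling genes these lists lay at percentiles 5.77 and 15.1. Their excess was then -0.53 over 14 genes and -0.26 over 33, against -0.95 and -0.70. With no matching they lay at percentiles 58.0 and 57.7. The ceiling, the smaller number of genes and the choice of matching cannot be told apart here. Only ZNF and mitosis stayed outside under every alternative run for all lists. Matched on the DMSO half-life, the excess over random lists was 0.21 for ZNF, against 0.54, and -0.51 for mitosis, against -0.52. Matching on motif class was not run for ZNF. ZNF genes had a median of 18 far coding motifs, and their median log2 ratio of 0.50 was near the 0.48 of genes with 10 or more such motifs. With both half-lives between 0.5 and 24 h, 3 of 16 lists stayed outside: ZNF, chromatin regulators and mitosis. Matched on the DMSO half-life, 3 of 18 did: ZNF, m6A factors and mitosis.

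The other 9 lists lay within the central 95%. Their members were named within 0.5 to 24 h, and some outside that range had more extreme ratios. JUND (10.8-fold longer-lived), EDC3 (14.3-fold longer-lived), GINS3 (ceiling in STM2457) and CDC45 (6.93-fold shorter-lived) are examples, chosen after their values were seen. Of 13 genes of mitochondrially encoded mRNAs, 4 were longer-lived and 1 shorter-lived (median 0.34). MT-CYB was 1.97-fold longer-lived and MT-ND6 1.73-fold shorter-lived. MT-ATP6, also longer-lived and chosen after its values were seen, went from 5.38 h to the ceiling in STM2457. Of 14 immediate early and short-lived regulators, 5 were longer-lived and 1 shorter-lived (median 0.27). ID2 went from 0.748 to 1.37 h, ATF3 from 0.795 to 1.31 h, MCL1, an anti-apoptotic factor, from 1.73 to 2.69 h and ZFP36L1, a decay factor for AU-rich mRNA, from 0.607 to 0.921 h. JUN went from 1.14 to 0.656 h, while IER5, IER2 and ID1 had log2 ratios of -0.48, -0.33 and -0.26, within 1.5-fold.

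Of 22 long non-coding and snoRNA host RNAs, 7 were longer-lived and 2 shorter-lived (median 0.36); DANCR was 2.22-fold longer-lived and NORAD 1.56-fold shorter-lived. Of 15 integrated stress response genes, 7 were longer-lived and 4 shorter-lived (median 0.32), with CHAC1, which degrades glutathione, from 0.565 to 2.90 h and PSAT1, of serine synthesis, from 19.2 to 9.84 h. Of 13 p53 targets, 2 were longer-lived and 5 shorter-lived (median 0.07), with XPC 3.58-fold longer-lived and FDXR 2.56-fold shorter-lived. Of 6 interferon-stimulated genes, 2 were longer-lived and 1 shorter-lived (median 0.11); IFITM1, which overlaps IFITM2, had a log2 ratio of -0.12.

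Genes of RNA decay and DNA replication had medians below 0, but so did their matched random lists. In the order below, random medians were -0.11, -0.11 and -0.09, and the lists lay at percentiles 16.62, 40.56 and 11.45. Of 23 deadenylation, decapping and 5′-3′ decay genes, 4 were longer-lived and 8 shorter-lived (median -0.29); LSM1 was 2.53-fold longer-lived and EDC4, a decapping scaffold, 1.97-fold shorter-lived. Of 18 nonsense-mediated decay and exon junction factors, 2 were longer-lived and 4 shorter-lived (median -0.17), with UPF3A 2.79-fold longer-lived and SMG6, an endonuclease, 2.18-fold shorter-lived. Of 39 DNA replication genes, 7 were longer-lived and 13 shorter-lived (median -0.31), with POLD1 1.95-fold longer-lived and MCM6, of the replicative helicase, 2.32-fold shorter-lived.

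A pair of lists had fewer than 5 genes in the table, and their members were named after their values were seen. Of 3 replication-dependent histones, HIST1H1C and HIST1H4C were 1.83-fold and 1.61-fold shorter-lived, and HIST2H2BD, annotated as a pseudogene, had a log2 ratio of -0.39. The libraries read polyadenylated RNA, so these values need not describe all RNA of these genes. Of the markers of other cell types, 2 were in the table: COL1A1, a collagen, at 7.85 h in DMSO and 29.1 h in STM2457, and CDX2, an intestinal transcription factor, at 2.00 h in DMSO and the ceiling in STM2457.

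**Figure D2:**
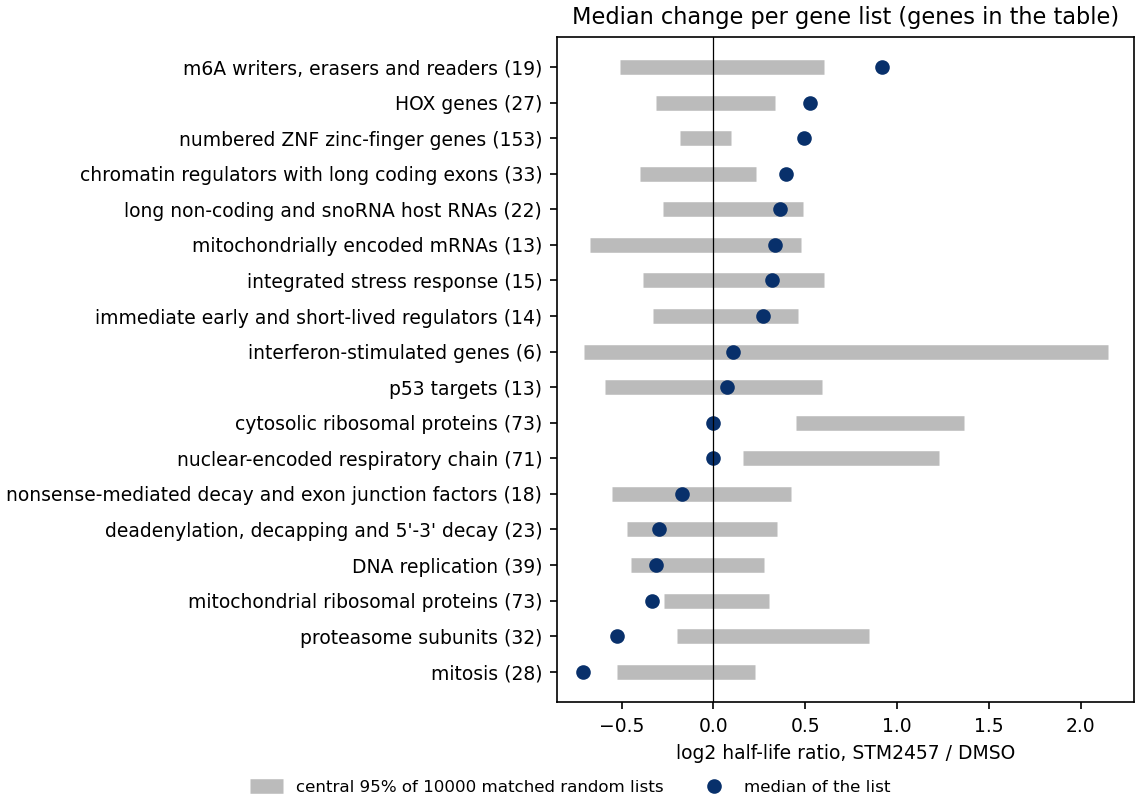
Median log2 ratio of half-lives, STM2457 over DMSO (horizontal), for the 18 gene lists with at least 5 genes, with the number of genes in brackets. Points are list medians and grey bars the central 95% of 10000 matched random lists; m6A factors lie highest at 0.92 and mitosis lowest at -0.71.

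The third comparison followed the series title, which concerns m6A in coding regions: half-lives were compared by the number of DRACH motifs, the sequence in which m6A occurs, in the coding region at least 100 nt from an exon junction. Such motifs are a stand-in from sequence and not a measurement of m6A. Genes with 10 or more such coding motifs (2154 genes) had a median log2 ratio of 0.48 (1.39-fold, under the 1.5-fold rule) and median half-lives of 2.79 h in DMSO and 4.12 h in STM2457. Genes with 0 (2142 genes) had a median of -0.22, with 9.30 and 7.32 h. The share of longer-lived genes was 45.8% with 10 or more motifs and 22.0% with 0, and the share of shorter-lived genes 10.5% and 32.7%.

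Genes with 1 to 3 motifs (2540) had a median of -0.22 and those with 4 to 9 (1691) a median of -0.02. The class with 10 or more lay at the 100th percentile of random lists matched on the mean half-life. The difference between 10 or more and 0 motifs was 0.69 on the log2 scale. It was 0.71 among genes with fewer 3′ UTR motifs and 0.66 among genes with more, split at the median of 18. Motifs in the 3′ UTR, counted in the same way, gave a difference of 0.10 between 10 or more (5657 genes, median 0.00) and 0 (450 genes, median -0.09). The 3′ UTR classes of 0, 1 to 3 and 4 to 9 lay at percentile 0 of matched random lists, with an excess of -0.13, -0.19 and -0.06. Coding motifs under 100 nt from a junction ran the other way, with a median of 0.61 at 0 motifs (281 genes) and -0.10 at 10 or more (6583 genes).

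Across genes, which are not independent replicates, the Spearman correlation of the log2 ratio was 0.263 with far coding motifs, -0.167 with near coding motifs, 0.06 with far 3′ UTR motifs and 0.01 with coding length. Genes with very many far coding motifs were not always longer-lived: AHNAK, a giant scaffold protein, had 380 motifs and went from 8.36 to 2.14 h (3.90-fold shorter). PCLO, a presynaptic scaffold, had 291 motifs and a log2 ratio of 0.21. Counted with no distance to a junction, the difference was 0.17, though 6 genes then had 0 motifs.

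**Figure D3:**
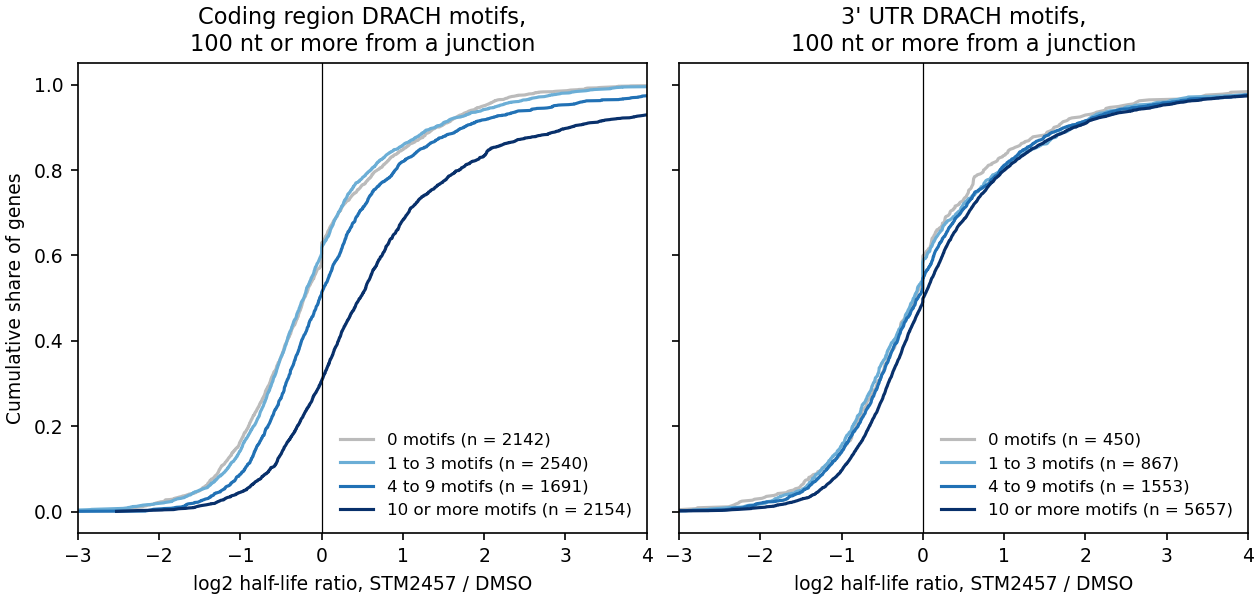
Cumulative share of genes (vertical) by log2 ratio of half-lives, STM2457 over DMSO (horizontal), in classes of DRACH motifs at least 100 nt from a junction, in the coding region (left) and the 3′ UTR (right). The coding class of 10 or more motifs (2154 genes, median 0.48) lies to the right of the class of 0 (2142 genes, median -0.22), and the 3′ UTR classes lie close together, with medians from -0.11 to 0.00.

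The baseline in DMSO set the groups apart before any treatment. Cytosolic ribosomal proteins had a median at the ceiling of 69.3 h, respiratory chain genes 31.6 h, proteasome subunits 17.4 h and mitochondrial ribosomal proteins 10.8 h, each at the 100th percentile of unmatched random lists. Immediate early regulators had 0.852 h, ZNF genes 1.79 h, HOX genes 2.12 h and chromatin regulators 2.34 h, each at percentile 0. DMSO half-lives were shorter in genes with more far coding motifs, with a Spearman correlation of -0.501 across genes.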

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

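Synthesis rates were outside the half-life comparisons, apart from the median given for mitosis genes, and 10 of the lists had a median log2 ratio of synthesis rates, STM2457 over DMSO, outside the central 95% of random lists matched on the abundance implied by the DMSO fit. The second matching, on the mean half-life, was chosen after these results were seen. Over 8993 genes the median was -0.06.

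Cytosolic ribosomal proteins had a median of 1.32, with 67 of 73 genes over 1.5-fold higher and 0 lower. Respiratory chain genes had 0.76, with 44 of 71 higher and 0 lower. At the half-life ceiling were 57 and 34 of these genes in STM2457, and 41 and 13 in both treatments. With both half-lives at the ceiling, the implied abundance rises by the same fold as the synthesis rate. Without read counts such a rise cannot be checked, so the size of these synthesis shifts stays open. Mitochondrial ribosomal proteins had 0.28, proteasome subunits 0.41 and HOX genes 0.23. ZNF genes had -0.27, with 31 of 153 over 1.5-fold lower and 5 higher. These 6 lists lay outside under both matchings.

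The remaining 4 lay outside when matched on abundance and inside when matched on the mean half-life. Chromatin regulators had a median of -0.27 (percentiles 0.16 and 5.09), m6A factors -0.24 (1.38 and 5.95), mitosis genes -0.18 (0.71 and 25.2) and interferon-stimulated genes 0.44 (99.0 and 76.6). Another 3 lists lay outside only when matched on the mean half-life: mitochondrially encoded mRNAs with 0.24 (51.3 and 99.6), immediate early regulators with 0.14 (88.9 and 98.7) and long non-coding RNAs with 0.24 (94.7 and 99.7). Across genes the synthesis ratio had a Spearman correlation of -0.353 with the half-life ratio; both come from the same fit.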

How the results depend on the processing

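No paired analysis was possible because the table has 1 fitted value per gene and treatment; leaving out replicates, intervals, limma settings and count-based tools were not run for the same reason, and depth, being unknown, sets no limit that could be computed. The alternatives without ceiling genes, of the most abundant genes for motifs, and matched on abundance were chosen after seeing the data. The median log2 ratio over all genes (-0.01) was -0.16 within 0.5 to 24 h, -0.13 without ceiling genes, -0.0531 above the median of implied abundance and 0.22 as a mean. Longer-lived genes numbered 1499 within 0.5 to 24 h, against 2562, where fewer genes enter; at 2-fold, 1773 genes were longer-lived and 1013 shorter-lived, against 2562 and 2244. Lists outside the central 95% numbered 3 matched on the DMSO half-life, 3 within 0.5 to 24 h and 4 without ceiling genes, against 9. The excess over random lists turned from below to above 0 for cytosolic ribosomal proteins (0.0106 with no matching, 0.00818 matched on abundance) and respiratory chain genes (0.00758 and 0.0271), whose medians are 0 at the ceiling. The motif difference (0.69) stayed above 0 in all 8 alternatives: 0.80 at 200 nt, 0.79 for GGAC, 0.78 per kb, 0.54 above the median abundance and 0.17 with no distance to a junction, where 6 genes had 0 motifs; within 0.5 to 24 h, without ZNF genes and without ceiling genes it lay between 0.67 and 0.71. The excess of the class with 10 or more over random lists (0.72) was 0.76 matched on coding length as well and 0.50 matched on the DMSO half-life, a matching added after seeing the data. The DMSO median was 4.93 h within 0.5 to 24 h and 5.21 h without ceiling genes, against 5.61 h. Beyond the constructions named, the cause was not tested.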

Other observations

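The groups by gene structure, the finer motif classes and the test on genes of high implied abundance were chosen only after the results were seen. Genes with their coding sequence in 1 exon (333 genes) had a median log2 ratio of 0.71, with 178 longer-lived and 48 shorter-lived in STM2457, and median half-lives of 2.55 h in DMSO and 4.97 h in STM2457. Those with 10 or more far coding motifs (205 genes) had a median of 1.08, and those with under 4 (39 genes) had -0.34. Genes whose longest coding part of an exon exceeds 1000 nt (1025 genes) had a median of 0.61, with 526 longer-lived and 88 shorter-lived.

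Antisense and lincRNA genes (144) had a median of 0.09 and processed pseudogenes (54) a median of 0.24, at the 84.9th and 51.1st percentile of matched random lists. By finer classes of far coding motifs, the median was 0.35 at 10 to 19 motifs (1022 genes), 0.52 at 20 to 39 (732 genes), 0.68 at 40 to 79 (296 genes) and 0.41 at 80 or more (104 genes). In genes without far coding motifs, 10 or more 3′ UTR motifs against 0 to 3 made a difference of 0.02; in genes with 10 or more far coding motifs it was 0.21.

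The longer half-lives of genes with many far coding motifs may reflect m6A-dependent decay, as a hypothesis. Coding length as the whole cause is argued against by 10 bins of coding length, within which genes with the larger share of motifs far from junctions were higher by a median of 0.53, above 0 in 9 of 10 bins and at 0.00 in the shortest. A short DMSO half-life is argued against by the 100th percentile among lists matched on it (excess 0.50, against 0.72 when matched on the mean half-life). The difference between 10 or more and 0 motifs was 0.64 among genes of high implied abundance within 0.5 to 24 h. It was thus not confined to genes of low implied abundance. That abundance comes from the same fit and precision is unknown, so poor measurement stays open. The partial rank correlation was higher for far than for near motifs by 0.46, as m6A-dependent decay needs, but exon structure moves with both counts and m6A was not measured.

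More genes reached the ceiling in STM2457. In the highest of 5 bins of implied abundance, 2.63 times as many genes reached it as in DMSO, which argues against low implied abundance alone. The other 4 bins gave 5.17 to 9.39 times. That abundance comes from the same fit and holds no read counts, so low read depth stays open. Of the 817 genes at the ceiling in STM2457 only, 26.1% exceeded 24 h in DMSO. This share argues against a drift of stable mRNAs. A fit in STM2457 that is not held to the measured abundance stays open: 99.6% of these genes imply more RNA than 6 h of synthesis without decay could add, but a half-life at the ceiling fixes that outcome, with unchanged synthesis too. Below the ceiling, 12.3% of 7950 genes also exceed that bound. PELO and TBCC are among them, and so are genes with smaller shifts, such as XPC and ZC3H13. The fold changes of such genes stay open, as at the ceiling. No such bound was set for falls in abundance, so the sizes of shorter half-lives were not checked this way.

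The shorter half-lives of mitosis genes were not accounted for by few coding motifs, since the list lay at percentile 0.08 when matched on motif class and mean half-life. A trade-off in the fit would need higher synthesis rates. Their median log2 ratio was -0.18, with 1 of 28 genes over 1.5-fold higher. The binomial 95% interval over genes, which are not independent replicates, was -0.30 to -0.09. This direction goes against such a trade-off, but it was made the criterion only after the percentiles were seen. The rule written first counted any median outside the central 95% in favour of changed synthesis estimates. The list met that rule matched on abundance (percentile 0.71) and not matched on mean half-life (25.2), so changed synthesis estimates stay open. A change in cell-cycle phase under STM2457 could also act, and was not tested.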
